A study of Danio rerio with 4 samples.

How the data were processed

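The series profiled nuclei of sorted jaw mesenchyme from zebrafish (Danio rerio) embryos at 2.5 days post fertilization with a multiome assay, in which open chromatin (ATAC) and messenger RNA are read from the same nucleus under a shared barcode. The 4 samples are the ATAC and RNA parts of 2 multiome libraries, 1 control and 1 mutant, so there is 1 library per genotype. Per the labels, control fish carried an nr5a2 reporter allele named GFP-CAAX-DBD-del, which drives the GFP used for sorting, together with a wild-type allele. Mutant fish carried the same GFP allele together with the oz3 mutant allele. Both also carried a scxa reporter with mCherry. Per the labels' protocols, heads were cut between eye and ear and dissociated, and live GFP-positive cells were sorted. Dead cells were excluded with Zombie Violet in the control sort and with DAPI in the mutant sort, so the viability stain differs between the genotypes.

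The authors processed the reads with Cell Ranger ARC 2.0.0 on the GRCz11 assembly, per the submitters' processing notes. The peak-calling settings are not given in the sources used here. The deposited files used here are, for each library, the list of barcodes that passed the software's filter and the list of features. How the authors treated doublets is not given in the sources used here. Barcodes alone do not allow a doublet call, so none was made and the numbers of nuclei may include doublets. Each feature list held the same 27410 gene rows, of which 27406 carried an Ensembl identifier and 4 were reporter sequences (mCherry, EGFP-CAAX, TagBFP and DsRedExpress). A further set of rows gave ATAC peaks as chromosome, start and end. The peak positions differed between the 2 lists, so each library had its own peak list. No read count, signal height, score or q-value per peak or per nucleus was analysed here. The sequencing depth of each library is therefore unknown, and a peak is known only as present in or missing from a list. Gene rows carried no position, and 24975 of the Ensembl identifiers matched the gene name table.

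A peak was called shared when it overlapped a peak of the other list by at least 1 bp, and otherwise control-only or mutant-only (together, library-only). Positions are GRCz11 coordinates exactly as in the files, which do not state whether starts are counted from 0 or from 1. Intervals on shares are exact (Clopper-Pearson) 95% binomial intervals over peaks. They cover counting error only, since peaks are not replicates of a genotype. With 1 library per genotype there is no test across genotypes, and no p-value is given.

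The genome was divided into windows of 100 kb and of 1 Mb by peak midpoint. For each window a score was computed from its control-only peaks c and mutant-only peaks m as (c − p(c + m)) / √((c + m)p(1 − p)), where p is the genome-wide control-only share of library-only peaks. The score is a rank and not a test. Runs were defined as consecutive control-only (or mutant-only) peaks with no peak of the other library between them, and those of 10 or more peaks are called long. To describe how far these quantities stood from an even mixing, the labels control-only and mutant-only were reassigned at random over all library-only peaks 100 times, keeping every position. Chromosome midpoints and distances to chromosome ends were measured against the end of the last peak on each chromosome.

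The overlap alternatives and the minimum width were chosen before the data were examined. The windows, runs, chromosome midpoints and chromosome ends were chosen after the data were examined. The rule for naming genes, fixed beforehand, ranked genes by the score of the peaks within 50 kb of their start sites. It could not be applied, because no GRCz11 gene annotation was used here. The same score was applied to windows instead, naming the 8 highest and 8 lowest that were not adjacent to a better one. For the same reason the 23 gene lists fixed beforehand (421 of their 428 genes are among the gene rows), the promoter shares and the 30 transcription factor motifs were not evaluated. Gene expression was not analysed here.

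The alternatives were a 50% reciprocal overlap, a requirement that no peak of the other list lie within 1 kb, a minimum width of 500 bp, and lists cut to equal number by keeping the widest peaks. Windows of 50 kb and 200 kb and windows shifted by 50 kb were added later. The scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap routine was checked on a jittered copy of the control peaks against bedtools 2.31.1, with a difference of 0 peaks. On randomly relabelled peaks with 50 planted windows of 100 kb, all 50 were among the 50 lowest scores.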

Results

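Open chromatin was profiled in nuclei of GFP-positive jaw mesenchyme of zebrafish controls and nr5a2 mutants at 2.5 days post fertilization. nr5a2 encodes an orphan nuclear receptor, and the comparison asks how its loss bears on chromatin accessibility in cells positive for the nr5a2 reporter. Both genotypes carried the reporter allele, controls beside a wild-type allele and mutants beside the oz3 allele. The controls were therefore not wild type at both copies. The control library held 4304 nuclei and the mutant library 6589, which is 1.53 times as many. The control library listed 230956 peaks covering 193.5 Mb, and the mutant library 210540 peaks covering 180.5 Mb. The balance of peak numbers depended on peak width. At or above 873 bp, the median width of both lists pooled, the control library listed 105653 peaks and the mutant library 116052. When control widths were scaled by the median width ratio of peaks matched one to one, the numbers were 111832 and 110223. Whether narrow peaks account for the longer control list is therefore undecided. All peaks lay on the 25 numbered chromosomes. There is 1 library per genotype, so every difference below is between these libraries, has no replicate check and cannot be separated from differences in depth or sorting. The depth of each library is unknown. The gene rows gave nr5a2 as ENSDARG00000100940 without a position, so the peaks at the nr5a2 locus were not analysed here and the labels could not be checked against it.

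Most listed peaks were common to both libraries, although the overlap that randomly placed peaks would give was not measured. Of the control peaks, 77.4% (exact binomial interval 77.3% to 77.6%) overlapped a peak of the mutant library. Of the mutant peaks, 85.0% (84.8% to 85.2%) overlapped a control peak. Bases covered in both libraries amounted to 145.1 Mb, or 63.4% of the bases covered in either. Among the 177442 peaks that matched one to one, the midpoints differed by a median of 25.5 bp and the mutant peak was a median of 1.01 times as wide as its control partner. The number of peaks per 100 kb window was also alike, with a Spearman rho of 0.90 across 13138 windows, which are not independent replicates.

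The 100 kb windows with the most peaks, ranked by the sum of both libraries, a choice that favours windows dense in both, held few unmatched peaks. Chromosome 4 from 17.0 to 17.1 Mb held 48 peaks in each library, of which 3 were control-only and 4 mutant-only. Chromosome 11 from 44.7 to 44.8 Mb held 47 in each, with 1 unmatched in each. Chromosome 22 from 16.9 to 17.0 Mb and chromosome 23 from 29.0 to 29.1 Mb each held 45 control and 44 mutant peaks. In the former, 3 were control-only and 2 mutant-only, and in the latter 6 and 5. Chromosome 11 from 21.9 to 22 Mb held 45 control and 41 mutant peaks, with 3 control-only and 0 mutant-only.

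Regions listed in a single library numbered 52101 in the control and 31583 in the mutant. Control-only peaks therefore made up 62.3% of the 83684 library-only peaks (exact binomial interval 61.9% to 62.6%). When the lists were cut to equal length by keeping the widest peaks, that share was 50.2%, near the even split that lists of the same length impose. Library-only peaks were narrower than shared ones in both libraries. Their median width was 835 bp against 872 bp in the control library and 854 bp against 883 bp in the mutant. Of the narrowest decile of control peaks 58.0% (57.4% to 58.6%) were found in the mutant library, against 86.6% (86.1% to 87.0%) of the eighth width decile. The corresponding shares of mutant peaks were 70.2% (69.6% to 70.8%) and 91.5% (91.1% to 91.9%). In the widest decile the shares were lower than in the eighth, at 79.5% for control peaks and 85.4% for mutant peaks. Control-only peaks lay a median of 1816 bp from the nearest mutant peak, and mutant-only peaks 2467 bp from the nearest control peak. More than 10 kb separated 3322 control-only peaks (6.38%, interval 6.17% to 6.59%) and 3653 mutant-only peaks (11.6%, interval 11.2% to 11.9%) from the other list.

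**Figure D1:**
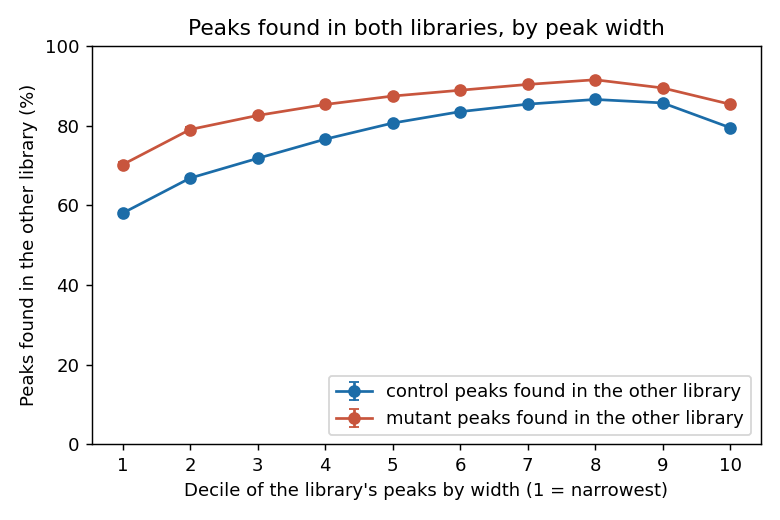
Share of each library's peaks that overlapped a peak of the other library (vertical axis, percent), by decile of the library's peaks ordered by width (horizontal axis). Points are single libraries and error bars, smaller than the points, are exact 95% binomial intervals; the share ran from 58.0% to 86.6% in the control library and from 70.2% to 91.5% in the mutant library.

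Over all peak widths, every one of the 25 chromosomes held more control than mutant peaks, but the balance of library-only peaks differed between chromosomes. The control-only share was lowest on chromosome 1, at 58.5% (exact binomial interval 57.0% to 60.1%). It was highest on chromosome 23, at 67.7% (66.0% to 69.3%), followed by chromosome 3 at 67.0% (65.5% to 68.4%). The interval lay above the genome-wide share on 6 chromosomes and below it on 8. These intervals treat peaks as independent, whereas library-only peaks of the same library lay together along the genome (below). They are therefore too narrow, and both counts may be too high. On chromosome 1 the share was 53.8% (51.6% to 56.1%) before the midpoint and 63.2% (61.0% to 65.3%) beyond it.

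The distal part of chromosome 4, beyond its midpoint at 39.0 Mb, lies in its heterochromatic and repeat-rich long arm and stood apart in both libraries. It held 24.9 control peaks and 16.6 mutant peaks per Mb. Before the midpoint these densities were 181.8 and 169.5 peaks per Mb. On no other chromosome did either side of the midpoint fall below 151.2 control peaks or 132.7 mutant peaks per Mb. Of the library-only peaks on distal chromosome 4, 453 were control-only and 129 mutant-only. This control-only share of 77.8% (exact binomial interval 74.2% to 81.1%) was higher than on either side of the midpoint of any other chromosome. With lists of equal number it was 69.0%, against 50.2% genome-wide.

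**Figure D2:**
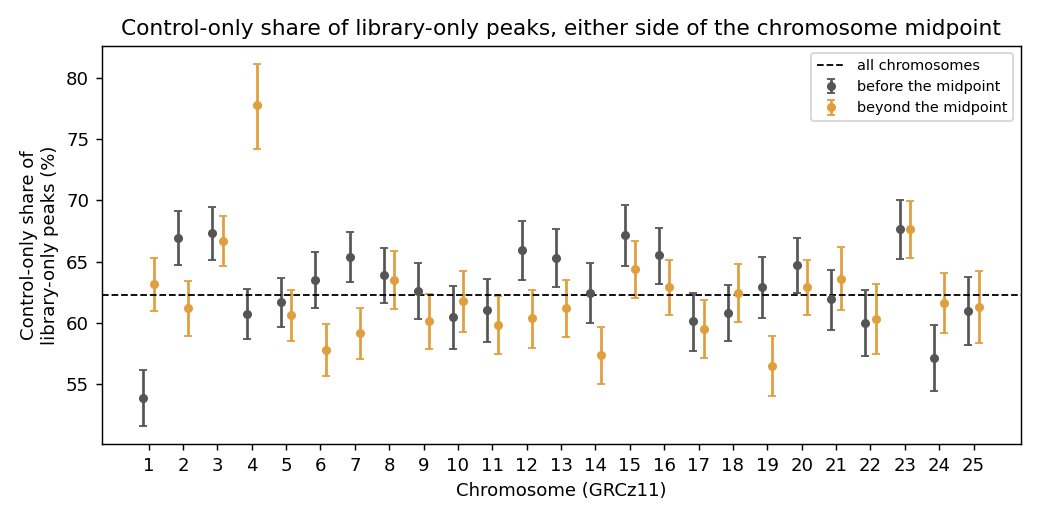
Control-only share of library-only peaks (vertical axis, percent; the axis does not start at 0) before and beyond the midpoint of each of the 25 chromosomes (horizontal axis). Points are shares, error bars exact 95% binomial intervals over peaks, and the dashed line is the genome-wide share of 62.3%; distal chromosome 4 lies highest at 77.8% and chromosome 1 before its midpoint lowest at 53.8%.

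At the scale of 1 Mb, library-only peaks of the same library lay together more than an even mixing would place them. The variance of the window scores was 3.65, against 0.901 to 1.08 in 100 random reassignments of the library-only labels. Scores above 3 were found in 61 windows and scores below −3 in 88, against at most 4 and 5 in the reassignments. Control-only peaks were most in excess on chromosome 23 from 44 to 45 Mb, with 83 control-only and 8 mutant-only peaks. Chromosome 22 from 2 to 3 Mb followed with 70 and 9, chromosome 8 from 0 to 1 Mb with 69 and 11, and chromosome 1 from 55 to 56 Mb with 66 and 10. The other 4 named windows of this direction lay on chromosome 20 from 2 to 3 Mb, chromosome 7 from 1 to 2 Mb, chromosome 2 from 13 to 14 Mb and chromosome 4 from 73 to 74 Mb. Mutant-only peaks were most in excess on chromosome 1 from 4 to 5 Mb, with 71 mutant-only and 29 control-only peaks. Chromosome 22 from 14 to 15 Mb had 56 and 20, chromosome 18 from 1 to 2 Mb 58 and 22, and chromosome 12 from 41 to 42 Mb 54 and 20. The remaining windows of this direction were chromosome 19 from 39 to 40 Mb, chromosome 4 from 23 to 24 Mb, chromosome 12 from 39 to 40 Mb and chromosome 17 from 13 to 14 Mb. In each of these 8 windows the mutant library listed more peaks than the control library, for example 203 against 161 on chromosome 1. The choice of windows by their mutant-only excess largely brings this about, so it is no separate result. The named windows with a control-only excess, except that on chromosome 2, had midpoints within 5 Mb of a chromosome end. So did the windows with a mutant-only excess on chromosomes 1 and 18. Among these windows only that on chromosome 8 had its midpoint within 1 Mb of an end. How many of all 1 Mb windows lie within 5 Mb of an end was not counted, so these positions show no excess near the ends. Shares by distance to chromosome ends are given below.

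**Figure D3:**
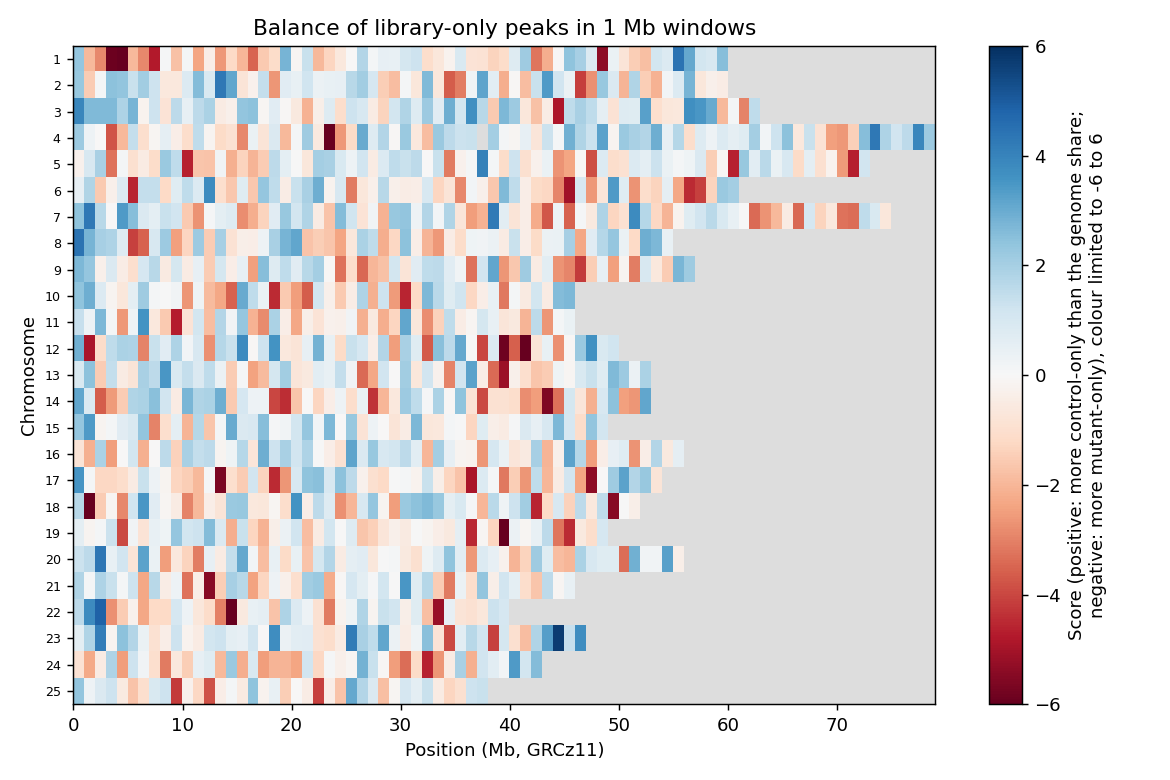
Score of each 1 Mb window by position (horizontal axis, Mb on GRCz11) and chromosome (vertical axis). Blue marks more control-only and red more mutant-only peaks than the genome-wide share gives. Grey marks positions without a score, either beyond the last window or in a window without library-only peaks. The extremes are 5.70 on chromosome 23 from 44 to 45 Mb and −6.86 on chromosome 1 from 4 to 5 Mb.

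Among windows of 100 kb, chromosome 10 from 1.5 to 1.6 Mb held 21 control-only and 0 mutant-only peaks beside 11 shared ones. Chromosome 12 from 0.5 to 0.6 Mb held 19 and 0, chromosome 20 from 2.0 to 2.1 Mb 18 and 0, and chromosome 3 from 56.7 to 56.8 Mb 17 and 0. The last of these held no mutant peak at all. The other named windows of this direction were on chromosome 19 from 0.6 to 0.7 Mb and from 11 to 11.1 Mb, chromosome 23 from 44.5 to 44.6 Mb and chromosome 7 from 1.0 to 1.1 Mb. In the other direction, chromosome 18 from 49.6 to 49.7 Mb held 13 mutant-only and 0 control-only peaks. Chromosome 22 from 14.9 to 15.0 Mb held 15 and 1, chromosome 14 from 37.3 to 37.4 Mb 12 and 0, and chromosome 1 from 43.2 to 43.3 Mb 11 and 0. The others were on chromosome 17 from 13.9 to 14.0 Mb, chromosome 3 from 61.8 to 61.9 Mb, chromosome 11 from 26.9 to 27.0 Mb and chromosome 14 from 43.9 to 44.0 Mb. The highest score in the 100 reassignments was 3.21 and the lowest −4.26, and 3 of the 8 named windows in each direction went beyond these. Which windows ranked highest depended on the grid, since 3 of the 16 overlapped a window named when the windows were shifted by 50 kb.

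Independently of any grid, 29 stretches held 10 or more consecutive control-only peaks with no mutant peak between them, on 14 chromosomes. Mutant-only peaks formed 10 such runs on 9 chromosomes. The random reassignments gave at most 5 long control-only runs and at most 1 long mutant-only run. With lists of equal number there were 15 control-only and 10 mutant-only runs. The control-only runs spanned a median of 74.4 kb (range 23.1 to 755.1 kb) and the mutant-only runs a median of 52.2 kb (25.1 to 107.1 kb).

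The longest control-only run counted 17 peaks on chromosome 3 from 56711309 to 56800288, a length that 1 of the 100 reassignments also reached. The nearest mutant peaks on its sides were 170.9 kb apart. Runs of 16 peaks on chromosome 4 (45371324 to 45537606), 15 on chromosome 7 (1141017 to 1227824) and 15 on chromosome 1 (55416588 to 55729217) followed. Chromosome 7 held further runs of 11 peaks from 1047180 to 1090213 and 12 from 1846298 to 1961564, and near its other end a run of 12 from 73389521 to 73423422. Chromosome 4 held 6 of the 29 runs, of which 5 lay beyond its midpoint and 1 at 33376098 to 33428111. The longest mutant-only run counted 13 peaks on chromosome 16 from 51473246 to 51548499. Runs of 11 mutant-only peaks lay on chromosome 24 (36850166 to 36881302), chromosome 3 (55113712 to 55148057) and chromosome 10 (18171869 to 18278960). A run of 10 on chromosome 22 (14952374 to 14977487) lay within the 1 Mb window named above for its mutant-only excess. The genes, exons and introns within these stretches were not analysed here, because no GRCz11 gene annotation was used.

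**Figure D4:**
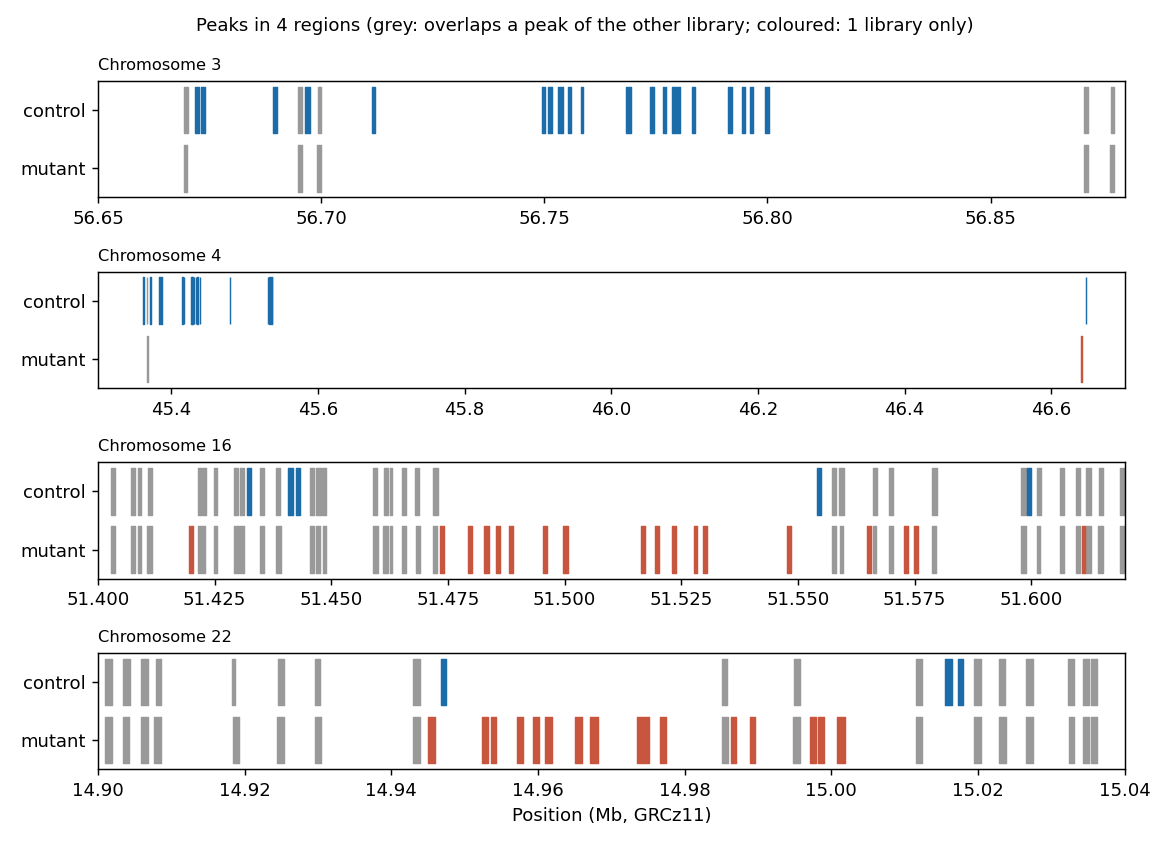
Peaks of the control and mutant libraries (rows) along 4 regions of GRCz11 (horizontal axes, Mb; bars drawn from peak start to peak end). Grey bars overlap a peak of the other library and coloured bars do not; on chromosome 3 the run of 17 control-only peaks faces no mutant peak, and on chromosome 16 the run of 13 mutant-only peaks faces no control peak.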

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

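The direction of the comparison held under the overlap settings and the minimum width of 500 bp, while several shares moved by more than their counting intervals. Outside these settings, at or above a common width of 873 bp, the direction of the peak numbers turned. The control library then had 105653 peaks and the mutant library 116052. With control widths scaled by the median ratio of matched pairs, the numbers were 111832 and 110223. With a 50% reciprocal overlap, 76.8% of control and 84.3% of mutant peaks were found in the other library, and the control-only share of library-only peaks was 61.8%. When a peak within 1 kb counted as found, these values were 83.8%, 88.7% and 61.0%. With peaks of at least 500 bp, 84.7% of mutant peaks were found and the control-only share was 61.6%. With lists of equal number the 3 values were 79.4%, 79.5% and 50.2%, and the long control-only runs numbered 15 in place of 29; the lists were cut to the same length, which by itself brings the share close to even. Long mutant-only runs numbered 9 or 10 in every one of these settings, and the variance of 1 Mb scores lay between 3.12 and 3.89. The control-only share on distal chromosome 4 was 69.0% with lists of equal number and at least 77.1% in the other settings. All 16 named windows of 100 kb kept their direction in these 4 settings. They had been chosen for extreme scores on largely the same peaks, so a change of direction was unlikely. Of the 16, 7 overlapped a window named at 50 kb, 5 at 200 kb and 3 after a shift by 50 kb. The motif, promoter, gene list and nr5a2 locus alternatives were not run, because no genome sequence or gene annotation of GRCz11 was used. No replicate could be left out with 1 library per genotype. Depth limits all of these values: a peak missing from a list is not shown to be closed chromatin.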

Other observations

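The tests on nuclei number, on wide peaks, on chromosome 4 and on random placement were chosen after the results they measure had been seen, and the values by distance to chromosome ends and by peak density were also chosen after the data were examined. Chromosome ends differed from chromosome interiors. Within 1 Mb of an end, 3326 control-only and 1367 mutant-only peaks were listed, a control-only share of 70.9% (exact binomial interval 69.5% to 72.2%). From 1 to 2 Mb the share was 63.7% (62.1% to 65.2%), and from 2 to 5 Mb it was 62.4% (61.4% to 63.3%). More than 5 Mb from the ends the share was 61.5% (61.2% to 61.9%). With lists of equal number the share near the ends was 55.4%, against 50.2% genome-wide. Windows of 1 Mb in the lowest quintile of peak density had a control-only share of 65.9% (65.0% to 66.8%), and the other quintiles lay between 60.8% and 62.9%. There were 34 windows of 100 kb with at least 4 control and 0 mutant peaks, and 6 with at least 4 mutant and 0 control peaks.

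The control library had the longer peak list although it had fewer nuclei. The number of nuclei argues the other way as the whole cause, since the mutant library had 1.53 times the nuclei and 0.912 times the peaks. Narrow peaks called in the control library alone stay open as a cause. At or above a common width of 873 bp the control library had 0.910 times as many peaks as the mutant library, and below it 1.33 times as many. When control widths were scaled by the median ratio of matched pairs, these ratios were 1.01 and 1.19. Control-only peaks at or above the common width outnumbered mutant-only ones, 1.30 times with raw widths and 1.47 times with scaled control widths (1.65 times over all widths). These peaks had been matched against all peaks of the other library, narrow ones included. The longer control list by itself leaves fewer mutant peaks unmatched, so this excess does not weigh against narrow peaks as a cause. Reads per nucleus, the share of reads in peaks and the different viability stains remain open, and so does a difference between the genotypes; none of these can be tested from peak positions.

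Library-only peaks of the same library lay together along the genome. Random placement is argued against by the variance of the 1 Mb scores, 3.65 against a highest value of 1.08 in 100 reassignments. Local peak density, taken in quintiles, did not remove the pattern, as the variance was 3.59 when the expected share was set separately in each quintile. The lowest quintile held windows of 3 to 235 peaks, and density within a quintile was not adjusted for. A regional difference in accessibility between the genotypes, a difference in the cell types within the sorted populations and a technical bias that follows base composition are all possible, and base composition was not tested because no sequence was used.

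The long control-only runs numbered 29, against at most 5 in 100 reassignments, so random placement does not give them. Weak peaks near the calling limit remain possible. The peaks in these runs had a median width of 839 bp. This lay between the 835 bp of all control-only peaks and the 872 bp of shared ones, which decides nothing. Run by run, the median width ranged from 725.5 bp to 918.5 bp. In the longest run, on chromosome 3, it was 753 bp, below that of all control-only peaks. Distal chromosome 4, beyond its midpoint, held 17.2% of the runs (exact binomial interval 5.85% to 35.8%) but 0.869% of the control-only peaks. The latter is not the share of runs that even mixing would place there, because every shared peak ends a run. Long runs in that region were not counted in the reassignments. Whether a property of that region bears on the 5 runs there is therefore undecided. Another 23 runs lie on other chromosomes and by themselves exceed the highest reassignment, so that region is not the whole cause; whether the chromosome 4 run before the midpoint belongs with the 5 was not tested. A list of peaks does not separate closed chromatin from sequence to which no reads mapped, and read coverage or genotypes over these stretches, which would separate them, were not analysed here.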
